A study of Homo sapiens with 2 samples.

How the data were processed

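RNA was sequenced from 2 cultures of ureteric bud cells made from 1 human iPSC line, collecting duct progenitors on day 10 and tip colonies on day 6, with 1 library per group. Per the labels' protocols, iPSCs were carried through intermediate mesoderm and nephric duct stages to ureteric bud organoids. The media of the nephric duct and organoid steps held a WNT-activating GSK3 inhibitor, a retinoic acid receptor agonist, an inhibitor of BMP receptors, FGF8 and GDNF. Per the labels' protocols, organoids were then dissociated and their cells reseeded with GDNF, FGF1, the retinoid agonist and the GSK3 inhibitor. The protocol text used here breaks off at that step, so the medium of each sampled culture is not given in the sources used here. The labels describe dissociation into single cells before RNA isolation, and each library was treated here as the bulk RNA of a culture. Because day, culture and library differ together, they cannot be separated. The groups were taken from the labels' cell subtype.

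The authors deposited FPKM values for 60662 annotated features, with feature type, exon coordinates and length, and per the file headers each column came from an alignment file whose name states that ribosomal RNA reads were removed. The genome build was GRCh38 per the submitters' processing notes. The aligner, the counting program and its strand setting are not given in the sources used here. Each length in the deposited table equalled the union of the listed exons in all 60662 features. FPKM multiplied by length summed to the same total in both deposited columns, so the values are per kilobase and per 1e+06 assigned reads, and a class of RNA that takes more of a library lowers all others. The smallest step of these products was 1/50 of a read, found from the size factors implied by the authors' mean values, whose product is 1 at 49.9998 steps per read. Reads that fit several features were therefore shared in fractions, and 66.6% and 66.0% of the features above 0 in collecting duct progenitor and tip colony came out at whole reads within 0.01. Values of paralogs, pseudogenes and overlapping genes are uncertain for this reason. All 37 mitochondrially encoded features were listed at 0 in both libraries, so they could not be compared. Another 407 features, nuclear copies of mitochondrial genes, held 3.07% of reads in collecting duct progenitor and 0.966% in tip colony. None of these copies is named as a gene result, but those past the filter below stayed in the gene counts and the scalings. The labels name poly(A) RNA as the molecule, yet RNAs without poly(A) tails were abundant in both libraries, so their levels can move with the library preparation.

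The authors deposited a table of the comparison made with DESeq2 version 1.20.0, per the submitters' processing notes. Per the file headers it holds the mean normalised count (a signal that is never negative), the log2 fold change with its standard error, the Wald score, the p-value and the adjusted p-value. Only 1 library stood on each side of that comparison, so its spread was not estimated within groups. The name of the authors' file gives the reverse order of the groups, and the sign was read from the values. All 4900 features of the deposited table at least 2-fold apart in FPKM on the scale below, counted before rows of the same symbol were summed, had the sign of collecting duct progenitor over tip colony. Of its 48874 rows, 33164 had no adjusted p and stayed out of the counts at adjusted thresholds. The authors' log2 fold changes differed from log2 ratios of the recovered reads by at most 0.14 over 20626 genes with at least 10 reads in both libraries.

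From the FPKM values, rows of the same symbol were summed (79 symbols had more than 1 row) and log2((tip colony FPKM + 1) / (collecting duct progenitor FPKM + 1)) was computed for the 18709 genes with an FPKM of at least 1 in either library. The pseudocount of 1 understates the difference of low genes. A gene was called higher in a culture at a 2-fold difference on this scale. Genes below the filter kept their values but were not counted. Folds in the text are ratios of FPKM without the pseudocount. Their 95% intervals are exact Clopper-Pearson intervals on the recovered reads, rounded to whole reads, and treat shared reads as if they were whole. A read on a gene of 1 kb was worth 0.0443 FPKM in collecting duct progenitor and 0.0355 in tip colony. Where a library had 0 reads, the fold is a lower limit against 3 counts per library, equal to 0.133 and 0.107 FPKM for such a gene.

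Before the data were examined, 33 lists of 460 genes in all were fixed, 10 of them for other cell types, together with the alternatives and the rule for naming genes. The rule took the 12 genes furthest each way among those with an FPKM of at least 5 in either library, leaving out sex-linked marker genes, mitochondrially encoded genes and names that are only clone identifiers. It also took up to 4 members of each list with the largest log2 ratios, and 7 genes whatever their values (RET, AQP2, WNT11, WNT7B, WNT9B, GATA3 and PAX2), which gave 145 genes, a few of which are not reported here. SOX9, ANOS1, ELF3, DKK1, HSPH1, PDGFRA and HOXC6 fall outside this rule and were named after their values were seen, as were genes named only in the closing section. Each list was described by the median log2 ratio of its members past the filter and by that median's percentile among 10000 random lists of protein-coding genes of the same size, matched on mean expression in 20 bins. These percentiles describe the libraries and are not p-values. Another 11 lists were chosen after the leading genes were seen and are used only in the closing section. The GABA-A receptor list was made because GABRG1 was a leading gene. The tests of RNA without poly(A) tails and of S phase were chosen after the results they measure were seen.

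No test was made, since each group had 1 library and the tables held 1 FPKM column for each. The tables held 0 columns of other samples. The alternatives were pseudocounts of 0.1 and 5, no filter and an FPKM of at least 5, TPM and median-ratio scaling, a 4-fold threshold, the highest row of each symbol and other thresholds on the authors' adjusted p. Added after the data were seen were protein-coding genes only, scaling to the sum of protein-coding genes other than histones, the size factors behind the authors' deposited table, random lists drawn from all features, and the authors' table at an adjusted p of 0.1 or an unadjusted p of 0.05. The calls were tested on simulated reads for 12796 genes of this comparison with 200 genes made different and counting error only. At a 4-fold difference towards tip colony 100% of 50 genes were called and at 2.5-fold 82.0%, at 0.25-fold 88.0% and at 0.4-fold 58.0%, and 0 of 12596 equal genes were called. A simulated list raised 4-fold reached percentile 100 and an unchanged list percentile 10.5. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.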

Results

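Gene expression was measured by RNA sequencing in 2 cultures of human ureteric bud cells derived from induced pluripotent stem cells (iPSCs). The ureteric bud is the embryonic epithelium that branches into the kidney's collecting duct system. Its tips hold dividing progenitors and its stalks go on to form the ducts. The first culture held collecting duct progenitors sampled on day 10 and the second held tip colonies sampled on day 6, with 1 library per group. The deposited values rested on 22582408 reads assigned to features in the collecting duct progenitor library and 28160166 in the tip colony library. Values above 0 were given for 42353 and 45590 annotated features. There were no replicates, so no difference could be tested against the spread between cultures. The intervals and lower limits given cover counting error only.

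The comparison asked how cells kept as tip colonies differed from cells carried towards the collecting duct. Of 18709 genes with an FPKM of at least 1 in either library, 2791 were at least 2-fold higher in tip colony and 2103 at least 2-fold higher in collecting duct progenitor on the log2(FPKM + 1) scale. Among the 12794 protein-coding genes the split lay the other way, with 1203 higher in tip colony and 1532 higher in collecting duct progenitor, and at least 8-fold differences numbered 59 and 128. Towards tip colony lay processed pseudogenes (552 higher there against 147), snoRNAs (284 against 19), lncRNAs (219 against 107) and snRNAs (153 against 52). Values of pseudogenes can hold reads shared with other genes. The split of all genes depended on scaling. Rescaling to TPM offset log2 ratios by −0.50, moved their median over all genes from 0.12 to −0.28, and gave 1399 genes higher in tip colony and 3405 higher in collecting duct progenitor. The offsets were −0.13 with median-ratio scaling and −0.17 with the size factors behind the authors' deposited table, which gave 2244 and 2463 genes. Scaling to the sum of protein-coding genes other than histones offset log2 ratios by only −0.02 and gave 2723 and 2141 genes. The TPM offset therefore came almost wholly from histones and features that are not protein-coding. Some of these RNAs lack poly(A) tails and can move with the library preparation.

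The genes furthest towards tip colony included ALDH1A1, which encodes a retinoic acid-producing aldehyde dehydrogenase and stood at 264 FPKM against 9.43 (28.0-fold, 95% counting interval 25.9 to 30.4). CXCR4, the receptor of the chemokine CXCL12, was 91.4-fold higher (50.9 to 184) and the immediate early transcription factor gene EGR2 reached 28.2 FPKM against 0.348. STC1, which encodes the secreted glycoprotein stanniocalcin, was 20.4-fold higher (17.7 to 23.6) and ALDOC, which encodes a glycolytic aldolase, 51.8-fold (35.2 to 79.5). GABRG1, a subunit gene of the GABA-A receptor, had 2992 reads in tip colony and 2 in collecting duct progenitor, a ratio of 1200 (332 to 9911). The transcription factor genes MSC (3 against 899 reads, ratio 240, 82.0 to 1167) and FEV (1 against 659 reads, ratio 528, 94.5 to 20905) were likewise near the floor in collecting duct progenitor. The microRNA locus MIR7845 had 53 reads in tip colony and 0 in collecting duct progenitor, at least 14.2-fold higher in tip colony against a floor of 3 counts per library. The remaining 3 of the 12 were the histone genes H2BC3 (17.8-fold), H4C9 (15.8-fold) and H4C6 (14.3-fold), whose near-identical copies can share reads.

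The gene furthest towards collecting duct progenitor was LCN2, which encodes the iron-siderophore binding protein lipocalin and stood at 157 FPKM against 0.111 (5649 against 5 reads, 1409-fold, 603 to 4341). SLPI, an antiprotease gene, stood at 79.4 FPKM with 0 reads in tip colony, at least 444-fold higher. The neutrophil chemokine gene CXCL5 was 179-fold higher (145 to 224), the natriuretic peptide gene NPPB 642-fold (250 to 2358) and AGR2, which encodes a protein disulfide isomerase of mucus-secreting epithelia, 278-fold (188 to 430). ANKRD1, a target of YAP signalling, was 96.5-fold higher (78.4 to 120). The smooth muscle actin gene ACTG2 had 3776 against 2 reads, a ratio of 2354 (651 to 19448). RARRES1 (386-fold), PLAAT4 (166-fold), ACER2 (81.3-fold), ARHGDIB (68.9-fold) and the ubiquitin-like gene UBD (50.2-fold) completed the 12 genes furthest towards collecting duct progenitor.

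**Figure D1:**
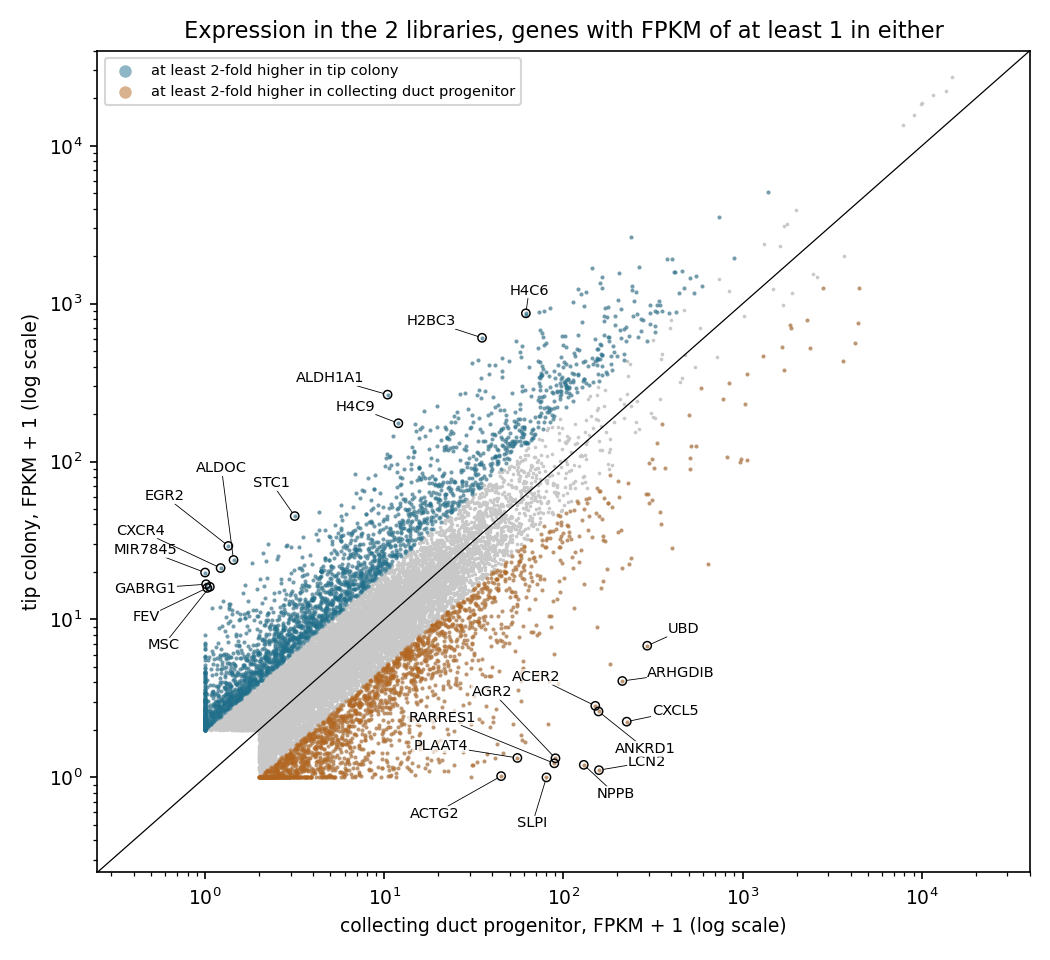
FPKM + 1 of each gene in collecting duct progenitor (horizontal, log scale) against tip colony (vertical, log scale) for the 18709 genes with an FPKM of at least 1 in either library, with the line of equality. Coloured points are the 2791 genes at least 2-fold higher in tip colony and the 2103 at least 2-fold higher in collecting duct progenitor as deposited (1399 and 3405 after rescaling to TPM), and circles mark the 12 named genes furthest each way.

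Ureteric bud tip genes were higher in tip colony. Of the 17 detected members of the list of 18, 12 were at least 2-fold higher in tip colony and 1 (ANOS1) at least 2-fold higher in collecting duct progenitor, with a median log2 ratio of 1.27, at percentile 100 of 10000 random lists matched on expression. RET, the receptor through which GDNF drives ureteric branching (chromosome 10, 43077064 to 43130351), stood at 22.3 FPKM in tip colony and 1.19 in collecting duct progenitor (18.7-fold, 16.1 to 21.8). Its co-receptor gene GFRA1 was 9.33-fold higher (8.75 to 9.95). WNT11, a ligand gene expressed at ureteric tips (chromosome 11, 76186325 to 76210736), was 53.8-fold higher (29.9 to 108). SOX9 was among the 4 members within 2-fold, at 48.1 FPKM in tip colony and 43.5 in collecting duct progenitor. After rescaling to TPM, 8 members were at least 2-fold higher in tip colony and 2 in collecting duct progenitor, with a median of 0.87.

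Stalk and trunk genes lay mostly the other way. Of 11 members, all detected, 7 were at least 2-fold higher in collecting duct progenitor and 2 at least 2-fold higher in tip colony (median −2.40, percentile 0), and these counts were the same after rescaling to TPM. The keratin gene KRT7 stood at 180 FPKM against 4.24 (42.4-fold, 38.7 to 46.5) and KRT23 was 57.2-fold higher (36.4 to 95.5). WNT7B, which encodes a ligand of the ureteric stalk (chromosome 22, 45920366 to 45977162), was 8.78-fold higher in collecting duct progenitor (7.71 to 10.0). The 2 members higher in tip colony were WNT9B, another stalk ligand gene (chromosome 17, 46833201 to 46886730), at 4.21 FPKM against 0.378 (11.1-fold, 8.54 to 14.8), and the calbindin gene CALB1 (17.3-fold).

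**Figure D2:**
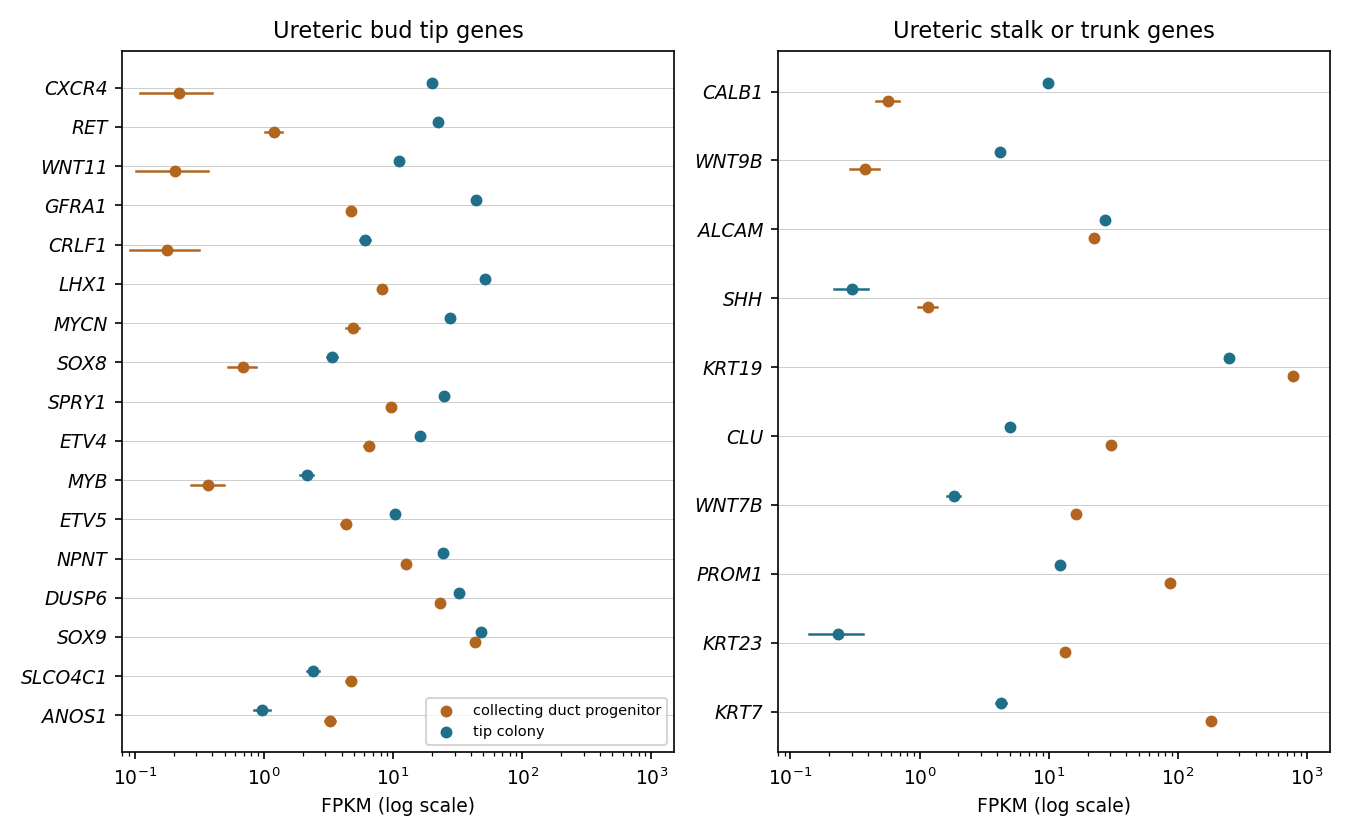
FPKM (log scale) of the 17 detected ureteric bud tip genes (left) and 10 of the 11 stalk or trunk genes (right) in the single library of each group, with bars for the 95% Poisson counting interval (some smaller than the point). Genes are sorted by log2 ratio, with 12 of the 17 tip genes at least 2-fold higher in tip colony and 6 of the 10 drawn stalk or trunk genes at least 2-fold higher in collecting duct progenitor (8 and 6 after rescaling to TPM).

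Genes shared along the ureteric lineage were expressed in both cultures. The transcription factor gene GATA3 (chromosome 10, 8045378 to 8075198) had 96.0 FPKM in collecting duct progenitor and 91.4 in tip colony, a ratio of 1.05 (1.02 to 1.08). PAX2, an early regulator of the nephric duct (chromosome 10, 100735603 to 100829941), was 5.52-fold higher in tip colony (5.26 to 5.80). The transcription factor genes EMX2 (4.80-fold) and SALL4 (6.62-fold) were also higher there, while the keratin gene KRT8 was 4.91-fold higher in collecting duct progenitor (4.83 to 4.98). Over the 12 detected members of 13, 4 were at least 2-fold higher in tip colony and 2 in collecting duct progenitor, with a median of 0.13 (percentile 54.4). After rescaling to TPM these counts were 4 and 4 and the median −0.23.

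Genes of the mature collecting duct were sparse in both libraries. Of 15 principal cell genes, 7 passed the filter, with 0 higher in tip colony and 1 higher in collecting duct progenitor (median −0.63, percentile 2.5). After rescaling to TPM 4 were higher in collecting duct progenitor (median −1.08), and without the filter on low values the median of all 15 was −0.11 (percentile 4.36). AQP2, the vasopressin-regulated water channel gene (chromosome 12, 49950741 to 49958881), lay below the filter at 0.915 FPKM in collecting duct progenitor and 0.0907 in tip colony, from 89 and 11 reads (10.1-fold, 5.38 to 20.9). The 1 gene past 2-fold on the log2(FPKM + 1) scale was SCNN1B, a subunit gene of the epithelial sodium channel (FPKM ratio 23.8, 12.7 to 50.5). As FPKM ratios its partner gene SCNN1G was 2.45-fold (2.05 to 2.93) and NR3C2 2.01-fold higher in collecting duct progenitor, and HSD11B2 2.52-fold higher in tip colony. Only 2 of 14 intercalated cell genes passed the filter, KIT, which encodes a receptor tyrosine kinase (7.27-fold higher in tip colony), and the carbonic anhydrase gene CA2 (median 1.38, percentile 99.05), and over all 14 the median was 0.03 (percentile 54.5). Of the 10 detected collecting duct transcription factor genes, EHF (7.24-fold), GRHL1 (5.06-fold), GRHL3 (3.72-fold) and ELF3 were at least 2-fold higher in collecting duct progenitor and HOXD8 in tip colony (5.68-fold), with a median of −0.08 (percentile 39.6).

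Urothelial genes were higher in collecting duct progenitor. Of 11 listed genes 4 were detected, and UPK2, UPK1B and KRT13 were at least 2-fold higher there (median −2.95, percentile 0). Over all 11, of which 7 lay below 1 FPKM in both libraries, the median was −0.44 (percentile 0.12). UPK2, which encodes a plaque protein of the bladder lining, stood at 18.9 FPKM against 0.316 (60.0-fold, 32.3 to 126), UPK1B had 710 against 2 reads (ratio 442, 122 to 3662), and KRT13 was 45.5-fold higher (21.4 to 130).

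Targets of WNT signalling were higher in tip colony. Of 12 detected members, 8 were at least 2-fold higher in tip colony and 1 (DKK1) at least 2-fold higher in collecting duct progenitor (median 1.48, percentile 100, and 7 and 2 after rescaling to TPM). The feedback regulator gene AXIN2 was 10.8-fold higher in tip colony (9.04 to 13.1), the transcription factor gene LEF1 23.5-fold (17.5 to 32.4), ZNRF3, which encodes a ubiquitin ligase for WNT receptors, 6.86-fold, and APCDD1 18.3-fold. Genes of ERK feedback were mixed, with 6 of 17 higher in tip colony and 2 in collecting duct progenitor (median 0.64, percentile 99.8). EGR1 (7.94-fold), IL17RD (5.02-fold) and IER3 (2.69-fold) were among those higher in tip colony. EGR1 is also a member of the immediate early and heat shock list, whose limits are given below. The phosphatase gene DUSP4 was 21.2-fold higher in collecting duct progenitor (19.4 to 23.2). After rescaling to TPM, 2 ERK feedback genes remained at least 2-fold higher in tip colony and 3 were higher in collecting duct progenitor, with a median of 0.23.

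Genes of retinoid handling divided between the cultures, with 3 of 13 at least 2-fold higher in tip colony and 5 in collecting duct progenitor (median 0.16, percentile 69.8, and −0.22 after rescaling to TPM). ALDH1A1 was higher in tip colony, whereas ALDH1A3, which encodes an enzyme of the same reaction, stood at 29.8 FPKM in collecting duct progenitor and 0.193 in tip colony (154-fold, 107 to 231). The retinoic acid-degrading enzyme gene CYP26A1 was 22.8-fold higher in tip colony (16.8 to 31.0) and the binding protein gene CRABP2 7.60-fold. Of 13 detected NOTCH pathway genes, 4 were at least 2-fold higher in tip colony and 0 in collecting duct progenitor (median 0.51, percentile 98.2), but the median lay inside the range of random lists drawn from all features (percentile 92.4). After rescaling to TPM 1 was higher in collecting duct progenitor and the median was 0.20. The 4 were the ligand gene JAG1 (4.04-fold) and the target genes HES1 (4.11-fold), HEY1 (16.5-fold) and NRARP (9.48-fold). The BMP and TGF-beta list also divided, with 5 of 14 higher in tip colony and 4 in collecting duct progenitor (median −0.24, percentile 12.1), and the median turned to 0.59 (percentile 96.9) over members with an FPKM of at least 5. BMP7 (4.79-fold) and the BMP target gene ID4 (3.66-fold) were higher in tip colony, and BMP2 (19.5-fold, 12.9 to 30.8) in collecting duct progenitor.

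Cell cycle genes were higher in tip colony. Of 25 members, 21 were at least 2-fold higher there and 0 at least 2-fold higher in collecting duct progenitor (median 1.62, percentile 100), and after rescaling to TPM the counts were 16 and 0. The mitotic kinase gene AURKB was 5.91-fold higher (5.13 to 6.83), and the ubiquitin-conjugating enzyme gene UBE2C 5.27-fold. TOP2A, which encodes a DNA topoisomerase, was 4.60-fold higher (4.40 to 4.80) and MCM2, a replicative helicase subunit gene, 4.75-fold. All 64 detected replication-dependent histone genes were at least 2-fold higher in tip colony under each scaling tried, with a median of 3.07. These messages lack poly(A) tails, and snoRNAs, a class of small RNAs without such tails, also took a larger share of reads in tip colony (0.861% against 0.179%). Targets of p53 lay towards collecting duct progenitor, with 9 of 12 at least 2-fold higher there and 0 in tip colony (median −1.20, percentile 0.02). The stress cytokine gene GDF15 was 10.4-fold higher in collecting duct progenitor (9.57 to 11.3), BBC3, which encodes a cell death effector, 4.54-fold, and the cell cycle inhibitor gene CDKN1A 3.36-fold (3.20 to 3.52).

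Genes of hypoxia and glycolysis were higher in tip colony. Of 16 members, 13 were at least 2-fold higher there and 0 in collecting duct progenitor (median 1.78, percentile 100, and 12 and 0 after rescaling to TPM). The glycolytic regulator gene PFKFB4 was 23.1-fold higher (19.7 to 27.4) and the mitophagy receptor gene BNIP3 was at 82.6 FPKM against 5.90. The lactate dehydrogenase gene LDHA was 7.58-fold higher (7.29 to 7.88) and the angiogenic factor gene VEGFA 8.20-fold. Immediate early genes were also higher in tip colony, with FOS at 14.2-fold (13.2 to 15.3), FOSB at 16.4-fold and JUN at 5.48-fold. Within the list that joins them to heat shock genes, 6 of 12 were at least 2-fold higher in tip colony and 1 (the chaperone gene HSPH1) in collecting duct progenitor (median 1.15, percentile 99.9), and 6 and 3 after rescaling to TPM (median 0.66). The labels describe dissociation into single cells before RNA isolation, and whether that step moved the immediate early genes was not tested. Genes of the unfolded protein and amino acid stress responses had 4 of 14 members higher in tip colony, led by DDIT4, which encodes an inhibitor of mTOR signalling (7.85-fold), and 1 in collecting duct progenitor (median −0.01, mean 0.28, percentile 42.7), which became 1 and 3 after rescaling to TPM. Their median was −0.34 after that rescaling and 0.53 (percentile 95.8) over members with an FPKM of at least 5. None of 16 cholesterol synthesis genes was 2-fold apart (median 0.08, percentile 67.9), whereas after rescaling to TPM 2 were higher in collecting duct progenitor and the median was −0.39.

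Interferon response genes were higher in collecting duct progenitor, at 6 of 11 against 0 in tip colony (median −1.04, percentile 0.07). HLA-B, which encodes a class I antigen-presenting chain and has close paralogs that can share reads, was 15.2-fold higher (13.6 to 17.1), its partner chain gene B2M 4.27-fold (4.10 to 4.45), the interferon-induced gene IFI6 9.58-fold and the transcription factor gene IRF1 4.46-fold.

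Genes of epithelial junctions were detected in both cultures, with 5 of 20 at least 2-fold higher in collecting duct progenitor and 1 in tip colony (median −0.54, percentile 0.57, 11 and 0 after rescaling to TPM). The claudin genes CLDN8 (5.54-fold) and CLDN1 (3.40-fold) and the splicing factor gene ESRP2 (3.10-fold) were higher in collecting duct progenitor and CLDN3 in tip colony (2.85-fold). The mesenchymal and matrix list was mixed, with 6 of 14 higher in collecting duct progenitor and 3 in tip colony (median −0.63, percentile 0.34). The matrix protein genes FN1 (17.5-fold, 16.8 to 18.2), TNC (17.7-fold, 15.3 to 20.7) and POSTN (8.64-fold) were higher in collecting duct progenitor, whereas VIM, the intermediate filament gene, reached 1351 FPKM in tip colony against 159 (8.51-fold, 8.39 to 8.64). Of 26 detected HOX genes 23 were within 2-fold, and HOXD8 (5.68-fold), HOXD9 (2.77-fold) and HOXD3 (2.73-fold) were higher in tip colony (median 0.00, percentile 49.3). HOXC8, at 1.19 FPKM against 0.118 (10.1-fold, 4.85 to 24.5), and HOXC6 (3.30-fold) were higher in collecting duct progenitor as FPKM ratios and within 2-fold on the log2(FPKM + 1) scale. Over the 15 HOX genes with an FPKM of at least 5 the median was 0.40 (percentile 97.9). After rescaling to TPM 1 HOX gene was higher in tip colony and 2 in collecting duct progenitor.

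Among markers of other cell types, those of stroma lay towards collecting duct progenitor, with 4 of 8 detected genes at least 2-fold higher there and 1 (PDGFRA) in tip colony (median −1.66, percentile 0, and −0.43 without the filter on low values). The contractile genes TAGLN (67.1-fold, 57.1 to 78.9) and ACTA2 (22.7-fold) and the collagen genes COL1A1 (8.60-fold) and COL3A1 (5.59-fold) were higher there. FN1, TNC, POSTN and ACTG2 shared that direction. Of 5 detected loop and distal tubule genes, MECOM (3.44-fold), POU3F3 (2.47-fold) and IRX1 were higher in tip colony (median 1.25, percentile 99.9, with 1 gene past 2-fold and a median of 0.77 after rescaling to TPM). Over all 12 listed genes the median was 0.05 (percentile 72.2). Of 5 detected pluripotency genes LIN28A and DPPA4 were higher in tip colony and POU5F1 in collecting duct progenitor (median 0.82, percentile 98.9, mean 0.20), none above 5 FPKM, and after rescaling to TPM 0 were higher in tip colony and 2 in collecting duct progenitor. Without the filter on low values the pluripotent (0.12), endoderm (0.01) and endothelium (−0.02) medians lay inside the range of random lists. FOXA1, an endoderm and urothelial transcription factor gene, was 8.61-fold higher in collecting duct progenitor (7.58 to 9.81), 1 of 2 detected endoderm genes (median −1.50, percentile 2.40). The single endothelial gene detected, CDH5, had 1.72 FPKM in collecting duct progenitor and 0.0584 in tip colony (log2 ratio −1.36, percentile 1.80). Nephron progenitor (5 detected, median −0.26), podocyte and proximal tubule (4, 0.28, and −0.14 after rescaling to TPM), neural (4, −0.46), muscle (3, −0.88) and blood genes (1, −0.41) lay within the central 95% of random lists. Without the filter on low values the nephron progenitor (0.10) and muscle (0.08) medians turned sign, and the neural median (−0.24, percentile 0.31) lay outside that range.

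In all, 20 of the 33 lists had medians outside or, for principal cell genes, exactly on the bounds of the central 95% of matched random lists, 10 towards each culture. For lists of independently drawn genes 1.65 would lie outside. Listed genes can vary together and some lists share genes, so that number is no test of the 20. Some of the 20 also rest on 1 or 2 detected genes. Over members with an FPKM of at least 5, medians lay further from 0 for ureteric bud tip (2.28), WNT target (2.27), interferon response (−1.93) and stroma genes (−2.74), while that of principal cell genes was −0.34 (percentile 27.2) and those of ureteric lineage (−0.07) and retinoid genes (−0.02) turned sign. Of 14 reference genes 11 were within 2-fold, and PGK1 (3.63-fold), RPLP0 (3.22-fold) and GAPDH (2.73-fold) were higher in tip colony (median 0.23, percentile 69.3). PGK1 is also a member of the hypoxia and glycolysis list, and RPLP0 encodes a ribosomal protein. After rescaling to TPM 2 reference genes were at least 2-fold higher in each culture and the median was −0.24.

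**Figure D3:**
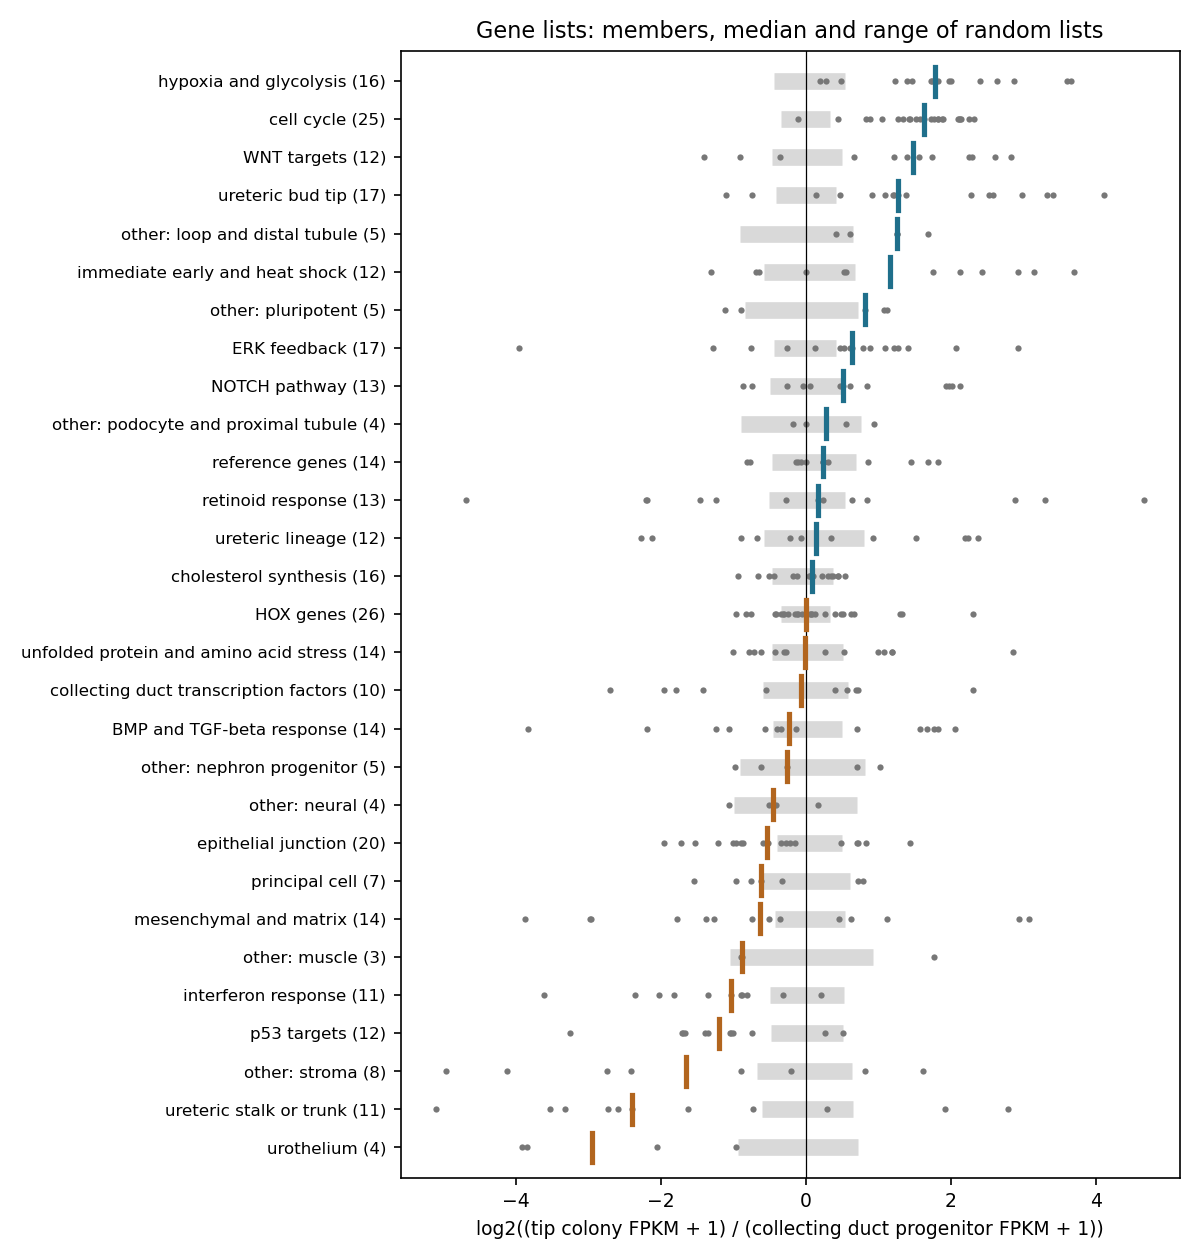
Log2((tip colony FPKM + 1) / (collecting duct progenitor FPKM + 1)) of the detected members (grey points) of each fixed gene list with at least 3 of them (their number in brackets), with the list's median (coloured bar, blue above 0 and brown below) and the central 95% of medians of 10000 matched random lists (grey band). Hypoxia and glycolysis (1.78) and cell cycle (1.62) stood highest and stalk or trunk (−2.40) and urothelium (−2.95) lowest, and after rescaling to TPM 5 medians change sign, ureteric lineage (−0.23), retinoid response (−0.22), cholesterol synthesis (−0.39), podocyte and proximal tubule (−0.14) and reference genes (−0.24).

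The authors' deposited table compared the same single libraries, with log2 fold changes of collecting duct progenitor over tip colony. Of 15710 genes with an adjusted p-value from DESeq2 in the authors' deposited table, 0 lay below 0.05, and the lowest value was 0.0900. At an unadjusted p under 0.05 the authors' deposited table held 1094 genes, 341 higher in tip colony and 753 higher in collecting duct progenitor. In the authors' deposited table CXCL5 had a log2 fold change of 7.66 (SE 1.84, DESeq2 adjusted p = 0.0900) and TAGLN 6.24 (SE 1.70, adjusted p = 0.0944). The values for the tip genes in the authors' deposited table were −4.05 for RET (SE 1.47, DESeq2 adjusted p = 0.369) and −5.58 for WNT11 (SE 1.72, adjusted p = 0.202). MSC, at −7.74 (SE 2.02, DESeq2 adjusted p = 0.0912) in the authors' deposited table, was 1 of 2 genes higher in tip colony among the 50 with an adjusted p below 0.1. The smallest standard error in the authors' deposited table was 1.01 on the log2 scale, and the 50 genes had log2 fold changes of at least 6.21 in size.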

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

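Protein-coding genes only, scaling to the sum of protein-coding genes other than histones, the authors' size factors, random lists from all features, and the authors' table at adjusted p 0.1 and unadjusted p 0.05 were chosen after the data were seen. Against 4894 genes at least 2-fold apart (2791 higher in tip colony, 2103 higher in collecting duct progenitor), a pseudocount of 5 gave 2042 (1251 and 791) and a 4-fold threshold 1007 (542 and 465), as shrunken ratios and a stricter threshold must. Counting protein-coding genes only left 2735, of them 1203 higher in tip colony, and an FPKM of at least 5 left 1348 higher in collecting duct progenitor, both with fewer genes counted. TPM gave 1399 and 3405, which follows from an offset of −0.50 on log2 ratios before the pseudocount. The median-ratio, coding-sum and size factor scalings and the other settings gave counts within 1.5 times of those as deposited. The authors' deposited table had 0 genes at an adjusted p of 0.05 or 0.01 and, at looser thresholds, 50 at an adjusted p of 0.1 and 1094 at an unadjusted p of 0.05. Of 198 recomputed medians of the 20 lists outside or on the bounds of the random range, 185 kept their direction and stayed outside, 12 kept their direction and no longer stood outside, and 1 reversed. Those 12 were medians of the principal cell, pluripotent, endoderm, intercalated cell, loop and distal tubule, endothelium and NOTCH lists, and the cause was not tested. The reversed value was the endoderm list without a filter on low values (0.0059), where its 8 genes below 1 FPKM enter. Of 127 recomputed medians of the other 13 lists, 2 came to lie outside, HOX genes with an FPKM of at least 5 (0.40) and neural genes without a filter on low values (−0.24), both with other members counted. The ureteric bud tip median ranged from 0.87 to 2.28 and the stalk or trunk median from −2.80 to −1.63. Of 870 recomputed values of the 145 named genes, 401 moved beyond their counting interval and 0 of the genes at least 2-fold apart changed direction. The pluripotent and endothelium lists had no member with an FPKM of at least 5, so that setting gave no value. Depth limits the folds of genes with fewer than 3 reads in a library, as for GABRG1, ACTG2 and UPK1B (2 reads each) and FEV (1 read). No paired analysis was possible because each group had 1 library with no replicate number. Leaving out columns, count models across columns and a replicate block were not run, since the tables held 1 FPKM column per group.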

Other observations

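The added lists, the ribosomal protein genes and MALAT1 were chosen after the leading genes were seen, and the tests of RNA without poly(A) tails and of S phase were chosen after the results they measure were seen. Epithelial defence genes shared the direction of LCN2, SLPI and CXCL5. Of 20 detected mucosal defence and NF-kB target genes, 13 were at least 2-fold higher in collecting duct progenitor and 0 in tip colony (median log2 ratio −1.31, percentile 0 of matched random lists). The adhesion molecule gene ICAM1 stood at 83.7 FPKM against 7.94 and TNFAIP2, a TNF-induced gene, at 66.7 against 7.32, while NFKBIA, the inhibitor gene that NF-kB induces, was at 78.8 and 74.0. Of 10 detected genes of the class I antigen presentation pathway, 7 were at least 2-fold higher in collecting duct progenitor and 0 in tip colony (median −1.54, percentile 0), among them the immunoproteasome gene PSMB10 (11.9 FPKM against 1.17). The other 3 were within 2-fold, and reads of paralogs among these genes can be shared.

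A pair of neighbouring GABA-A receptor subunit genes on chromosome 4 stood out in tip colony. GABRG1 (46035769 to 46124054) had 15.7 FPKM and GABRA2 (46248427 to 46475230) 12.1 FPKM there, against 0.0131 and 0.264 in collecting duct progenitor, and of 4 detected GABA-A receptor genes these 2 were at least 2-fold higher in tip colony (median 1.39). This list was made because GABRG1 was among the leading genes, so it adds no independent support. Of 15 detected YAP target genes, 6 were at least 2-fold higher in collecting duct progenitor and 0 in tip colony (median −0.69, percentile 0.34). The tissue factor gene F3 was among the 6, at 83.9 FPKM against 9.60. The YAP target ANKRD1, among the leading genes above, was further apart at 96.5-fold. Of 78 cytosolic ribosomal protein genes, 70 were at least 2-fold higher in tip colony and 1 in collecting duct progenitor (median 1.36), although after rescaling to TPM 25 were higher in tip colony (median 0.86). The nuclear long RNA MALAT1 was 2.50-fold higher in collecting duct progenitor.

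All 64 replication-dependent histone genes were higher in tip colony (median log2 ratio 3.07, quartiles 2.81 and 3.30). Gene length bias is argued against by 277 other coding genes shorter than 1000 bases, whose median was −0.026. A uniformly larger share of RNA without poly(A) tails in the tip colony library is argued against as the whole cause, since 23 other such RNAs had a median of 2.16 with an upper quartile of 2.42, but it may account for part of the difference. A larger share of cells in S phase is a candidate explanation for the rest, with a median of 1.57 over 9 replication genes and 0.36 over 10 histone genes whose messages carry poly(A) tails. The data leave open how much each contributed.

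Contractile genes (TAGLN, ACTA2, CNN1, MYL9 and ACTG2) were higher in collecting duct progenitor, with a median of −4.71. Fibroblasts or stroma in that culture remain possible. Of 13 detected fibroblast genes (22 listed, 1 shared with another list, 10 at 1 FPKM or more in tip colony) 5 were at least 2-fold higher in collecting duct progenitor (38.5%, exact 95% interval 13.9 to 68.4) and 4 in tip colony (5 and 1 after rescaling to TPM), COL6A1 was at 17.2 FPKM in both, and of the stroma list DCN had 0.727 FPKM in collecting duct progenitor against 0.105, while COL1A2 was 1.80-fold higher in tip colony. This share lies below the 50% set beforehand as counting against stroma, but its interval spans that value. The whole interval lies below the higher share set beforehand as counting for stroma. The 13 fibroblast genes had a median of 0.0006 (percentile 45.7 of matched random lists, and −0.47 after rescaling to TPM). The stroma list, by contrast, lay towards collecting duct progenitor (median −1.66, percentile 0). The interval treats the genes as independent and covers no spread between cultures. Stroma and the epithelium therefore cannot be told apart from this share. An actin and SRF programme in the epithelial cells is a candidate explanation, since 18 other actin and SRF target genes had a median of −1.43 and 13 were at least 2-fold higher in collecting duct progenitor, though bulk RNA does not locate them and stromal cells may carry them too.

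Glycolysis and hypoxia genes were higher in tip colony (median 1.78, and 1.04 over 12 glycolytic enzyme genes, 7 at least 2-fold higher there, percentile 99.99, and 0.56 and 5 after rescaling to TPM). The scaling of the libraries is argued against as the whole cause for the fixed list of 16 genes, whose lowest median over 4 other scalings was 1.28, and may set part of the size for the enzymes. Lower oxygen in the tip colonies may contribute and cannot be told apart from other causes here. Of 18 HIF target genes outside glycolysis, 38.9% were at least 2-fold higher in tip colony (7 genes), short of the share set beforehand as counting for this cause. Another 2, ANGPTL4 and LOXL2, were at least 2-fold lower. The median of the 18 was 0.78 (percentile 100 of matched random lists), above the value set beforehand as counting against this cause. It was 0.67 with median-ratio scaling, 0.77 with the coding sum and 0.62 with the authors' size factors. After rescaling to TPM it was 0.32, on the side counting against this cause. Fewer mitochondria in the tip colonies cannot be told apart either. The median of 35 nuclear respiratory chain genes was 0.17 as deposited, on the side set beforehand as counting against this cause. The median was on the same side with median-ratio scaling (0.06), the coding sum (0.15) and the authors' size factors (0.01). Only after rescaling to TPM was the median −0.30, between the values set as counting for and against it. Nuclear copies of mitochondrial genes, which can take mitochondrial reads, held a smaller share of reads in tip colony. The culture stage and medium of the groups stay open as untested explanations.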
